A study of Mus musculus with 14 samples.

How the data were processed

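Polyadenylated RNA of single dentate gyri from 14 slice cultures, 6 wildtype and 8 APPko, was measured by RNA sequencing. Per the labels' protocols, cDNA was made and amplified with a low-input kit (12 cycles), 10 ng of cDNA entered library preparation (10 further cycles), and libraries were read as 151 bp pairs. The deposited values are raw counts per gene symbol, 1 table per library, which the authors made with cutadapt 3.5, STAR 2.7.8a and featureCounts 2.0.1 on GRCm38 (mm10), per the submitters' processing notes. The strand setting of the counting and the treatment of multi-mapping and duplicate reads are not given in the sources used here. The 55291 row names equal the gene names of the gene annotation deposited by the authors, from which positions, gene types and exon lengths were taken. 107 symbols stand for more than 1 locus and share a row. Library amplification without molecular identifiers means that reads are not independent molecules. Depth was 16686909 to 31031126 counts per library.

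Each library was assigned to its genotype by its title. The 14 libraries were counted as separate samples because the labels call them biological replicates. No pair within a genotype held the same counts within sampling noise (chi-square over degrees of freedom 8.78 to 111, 43 pairs), which speaks only against a library deposited more than once. Genes were kept by edgeR's expression filter by genotype (22150 genes), and libraries were scaled by TMM. APPko was compared with wildtype by edgeR's quasi-likelihood test with robust dispersion estimates and no covariate, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. CPM values are TMM-scaled. Fold changes are given as APPko against wildtype from the fitted log2 value, and the ± values are SDs over 6 wildtype and 8 APPko libraries. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0 were used. The procedure was tested on simulated data over 21331 genes. Of the genes changed 1.5-fold 21.2% were recovered, of those changed 2-fold 61.5% and of those changed 4-fold 95.0%. There were 4 false calls among 21140 unchanged genes, and a shifted list was called with no other list beside it. The simulated genes varied independently of each other and without a GC trend between libraries. In the real lists the estimated correlation reached 0.52 (interferon response). The simulation therefore does not show how often camera calls lists of correlated genes by chance.

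31 gene lists fixed before the data were examined were tested on log2 CPM (prior count 2) with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether a list's genes move one way on balance. App was left out of every list. Scores per library (the mean over a list of log2 CPM minus each gene's mean) were compared by a two-sided exact permutation test, added after the data were seen. Genes near App were those within 10 Mb on chromosome 16, tested by a two-sided Fisher's exact test without App. Named genes followed a rule fixed before the data were examined: App, its homologues and genes of the sex chromosomes that mark the sex mix; the 10 higher and 10 lower genes with the smallest p and the 5 higher and 5 lower with the largest change among those past the threshold at a mean of at least 1 CPM; 2 genes with the smallest p of each list, or 4 where 3 or more passed; and up to 10 called genes within 10 Mb of App. Some genes that the rule names are not used here.

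Alternatives fixed beforehand were other library scalings, DESeq2, limma's voom with quality weights, other expression filters, protein-coding genes alone, mitochondrial genes or the neighbourhood of App left out, the replicate number as a block, a trend over gene length removed by offset, 1 surrogate variable, Y-linked expression as a covariate, libraries thinned to the smallest total, a test against a fold of 1.2, each library left out in turn and windows of 2, 5 and 20 Mb. Added after the data were seen were a trend over transcript GC content removed by offset (lowess span 0.3, GC known for 99.9% of tested genes), the header suffix as a covariate, f libraries alone, and the comparison without wildtype libraries 2 and 3. GC content was taken from GENCODE transcripts of the same build.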

Results

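Polyadenylated RNA was sequenced from dentate gyri cut out of mouse organotypic slice cultures, in which the entorhinal cortex stays attached to the hippocampus and its fibres still reach the granule cells. The slices were made at postnatal day 4 to 5 and matured for at least 18 days. 6 libraries came from C57BL/6J wildtype cultures and 8 from cultures of a gene-targeted line deficient in the amyloid precursor protein (APPko), and each library held the RNA of a single dentate gyrus. Total counts per library ran from 16686909 to 31031126, with a mean of 22144000 ± 5232100 in wildtype (SD, n = 6) and 25789000 ± 3697100 in APPko (SD, n = 8). The labels call the libraries biological replicates without saying which cultures shared an animal, so the p-values measure the spread between cultures. The column headers of the count tables end in f or m. 3 wildtype and 7 APPko libraries carried f, 3 wildtype libraries and 1 APPko library carried m, and the levels of Xist and of the Y-linked genes matched the suffix in 10 of 10 f libraries and 4 of 4 m libraries.

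The comparison asked how the dentate gyrus transcriptome differs when the amyloid precursor protein is missing. App itself (ENSMUSG00000022892.11, chromosome 16, 84949685 to 85173766, GRCm38) had the smallest p of all 22150 tested genes. Its level was 809 ± 131 CPM (counts scaled to library size) in wildtype (SD, n = 6) and 214 ± 17.9 CPM in APPko (SD, n = 8), a 3.78-fold lower value (log2 fold change -1.92, SE 0.11, edgeR adjusted p = 9.2e-09). Wildtype libraries lay between 679 and 964 CPM and APPko libraries between 182 and 231 CPM, so every library went with its label. The counts are summed over the gene, and they do not show which App exons the remaining reads cover. The homologues did not pass the test. Aplp1 had 207 ± 33.0 CPM in wildtype and 249 ± 24.1 CPM in APPko (edgeR adjusted p = 0.18). Aplp2 had 429 ± 66.1 and 429 ± 32.8 CPM, with a 95% interval of its log2 change from -0.22 to 0.22.

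Across the transcriptome, 209 genes were higher and 312 lower in APPko at an adjusted p under 0.05, App included, and 34 of the higher and 40 of the lower genes changed more than 2-fold. Among the genes with the smallest p that rose, Wdfy1, an endosomal adaptor of Toll-like receptor signalling (chromosome 1), went from 37.3 ± 5.70 to 76.6 ± 11.6 CPM, 2.06-fold (adjusted p = 0.00037). Ifitm3, an interferon-induced membrane protein, rose 1.84-fold from 145 ± 26.2 to 267 ± 31.5 CPM, and Fxyd1, a regulator of the sodium pump, rose 1.77-fold from 209 ± 32.4 to 369 ± 41.2 CPM (both adjusted p = 0.0018). 3 genes for secreted proteins were among them. Sod3, the extracellular superoxide dismutase, rose 2.54-fold from a low 1.29 ± 0.23 CPM, Gpx3, the plasma glutathione peroxidase, rose 3.04-fold to 146 ± 40.1 CPM, and Serpinf1, pigment epithelium-derived factor, rose 1.96-fold to 103 ± 22.3 CPM (adjusted p = 0.0018, 0.0059 and 0.0059). Cd52, Ifitm10 and the pseudogene Gm7536 rose 1.52-, 1.80- and 1.81-fold. Among the higher genes past the threshold with a mean of at least 1 CPM, Map3k7cl (3.18-fold), Cda (3.15-fold), Gpc1 (2.82-fold) and the ribosomal protein copy Rpl10-ps3 (2.68-fold) rose most beside Gpx3. Map3k7cl and Cda lay below 4 CPM in the mean of either genotype.

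Among the genes away from chromosome 16 that fell with the smallest p, Slitrk4 (126 ± 22.2 to 78.5 ± 7.40 CPM), Il1rapl1 (53.6 ± 11.5 to 29.7 ± 5.25 CPM) and Pcdhb16 (16.4 ± 1.49 to 10.2 ± 1.38 CPM) were 1.604-, 1.81- and 1.61-fold lower, with adjusted p of 0.0078, 0.011 and 0.011. Pdcd4, an inhibitor of translation initiation, fell 2.00-fold from 318 ± 108 to 159 ± 26.8 CPM. Capn11 and the unconfirmed transcript Gm43188 were 3.72- and 3.04-fold lower with wide spreads in wildtype (2.42 ± 1.45 and 15.4 ± 10.8 CPM). Wildtype libraries 2 and 3 stood apart, with TMM factors of 0.852 and 0.847 against 0.976 or more elsewhere. Without them 19 genes were higher and 16 lower, 33 of them among the 521, and leaving out single libraries gave from 38 genes (without APPko library 5) to 1436 (without wildtype library 4).

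12 genes passed the threshold in each of the 14 fits without a single library and in 7 further settings chosen after the data were seen. They were App, Gm49708, Btg3, Tiam1 and Zbtb21 on chromosome 16, all lower, and Wdfy1, Fxyd1, Ifitm3, Sod3, Serpinf1, B2m and Rtn2 elsewhere, all higher. Over all 23 alternative settings App and Wdfy1 passed in each, and the other 10 in 19 (B2m and Rtn2) to 22 (Btg3 and Tiam1). The setting without the neighbourhood of App left out Btg3, Tiam1 and Gm49708 by design, and it counts here as not passed. Protein-coding genes alone also left out Gm49708, which passed in 21. Btg3, Tiam1 and Gm49708 passed in each setting that tested them. Rtn2, an endoplasmic reticulum protein that lies outside the naming rule, was added to this list after its values were seen.

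**Figure D1:**
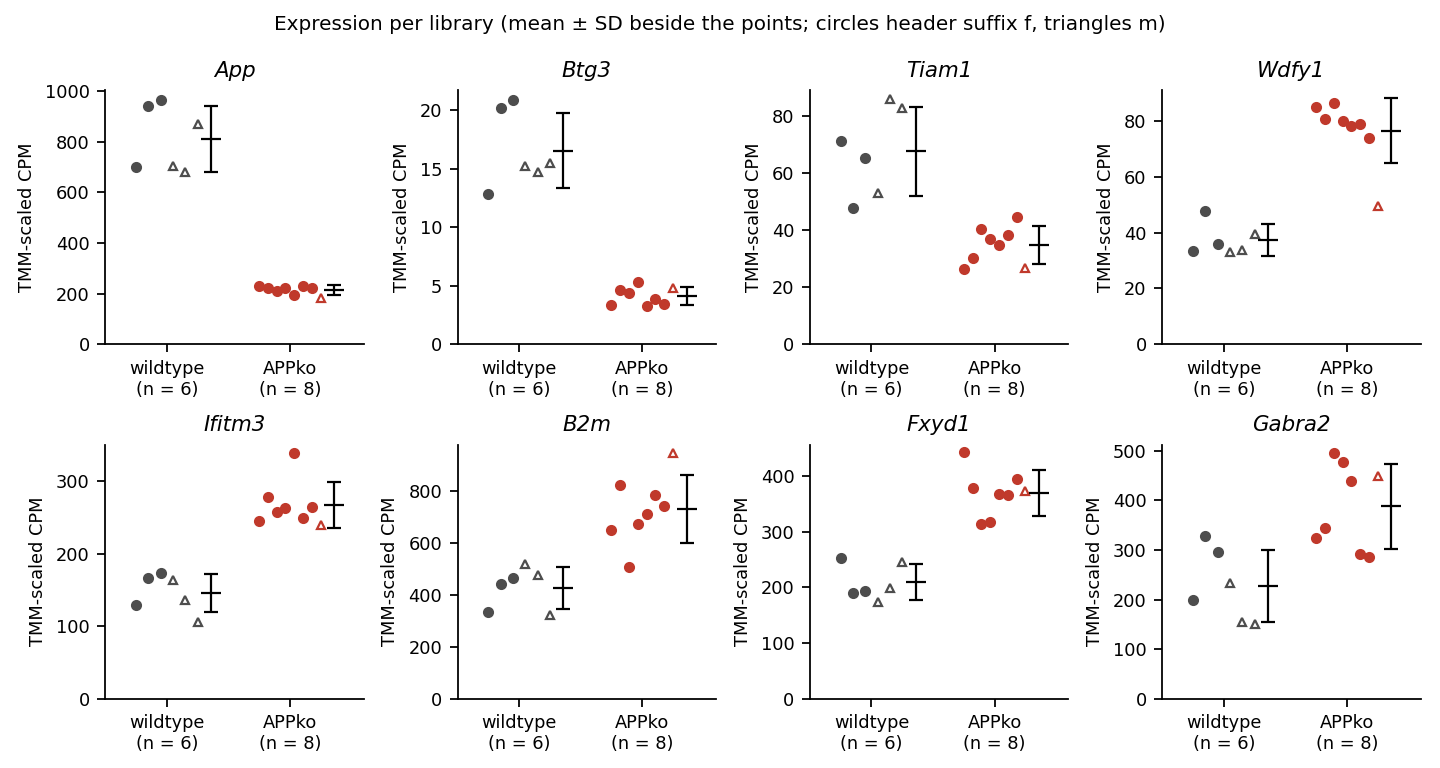
TMM-scaled CPM (y axis) of 8 genes in each wildtype (grey, n = 6) and APPko (red, n = 8) library, with the mean ± SD beside the points, circles for header suffix f and triangles for m. App lies between 679 and 964 CPM in wildtype and between 182 and 231 CPM in APPko, and for Wdfy1 a single APPko library lies at 49.5 CPM below the other 7.

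Genes close to App on chromosome 16 were compared with the rest of the genome, because a targeted allele carries its flanking DNA with it. Within 10 Mb of App, 10 of 123 tested genes passed the threshold (8.13%), against 510 of 22026 elsewhere (2.32%), an odds ratio of 3.73 (95% interval 1.73 to 7.18, two-sided Fisher's exact test p = 0.00066). Btg3, an antiproliferative factor 6.57 Mb from App, fell 4.00-fold from 16.6 ± 3.22 to 4.14 ± 0.78 CPM (SE of the log2 value 0.15, edgeR adjusted p = 4.3e-07). Tiam1, an activator of the GTPase Rac, 4.61 Mb away, fell 1.94-fold from 67.6 ± 15.5 to 34.8 ± 6.57 CPM (adjusted p = 0.0059). The transcripts Gm49708 and Gm36001, 5.17 and 5.37 Mb away, were at 3.62 ± 1.16 and 2.15 ± 1.201 CPM in wildtype and at 0.067 ± 0.068 and 0.25 ± 0.12 CPM in APPko, where they had 14 and 51 counts over all 8 libraries. Gm49228, a pseudogene inside App that overlaps none of its exons (85021622 to 85022017), fell from 2.13 ± 1.10 to 0.026 ± 0.036 CPM. It counts among the 10 although it lies within the targeted gene and not in flanking DNA. Map3k7cl rose 3.18-fold, Gm9843 and Cbr3 each rose 1.56-fold, and Ncam2 and 9530003O04Rik were 1.30- and 2.19-fold lower. Outside the window, Zbtb21, 12.8 Mb from App, fell from 76.2 ± 44.6 to 26.0 ± 3.22 CPM (log2 change -1.55, and -0.90 without wildtype libraries 2 and 3, which lay at 149 and 114 CPM), and Robo2, 10.5 Mb away, from 134 ± 23.8 to 97.1 ± 11.7 CPM. Zbtb21 shares exon sequence with C2cd2 on its own strand and Btg3 overlaps Cxadr on the other, and no source used here gives the strand setting of the counting. The odds ratio was 1.00 with DESeq2 (1801 calls, Fisher's exact p = 1.00) and 1.41 with the header suffix as a covariate (1446 calls, Fisher's exact p = 0.27), 2 settings that called more genes. It was 40.4 without wildtype libraries 2 and 3 and 1.73 without wildtype library 4 (Fisher's exact p = 0.064).

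**Figure D2:**
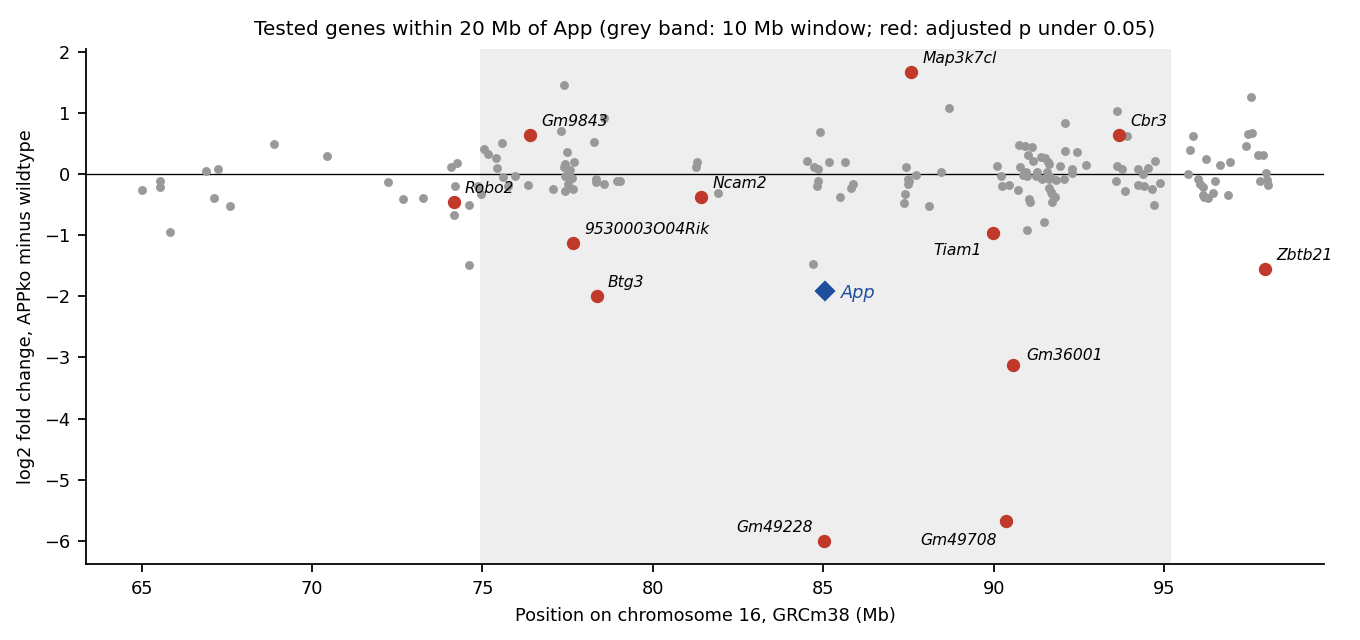
log2 fold change of APPko minus wildtype (y axis) of each tested gene within 20 Mb of App against its position on chromosome 16 of GRCm38 in Mb (x axis), with genes at an adjusted p under 0.05 in red, App as a blue diamond and the 10 Mb window as a grey band. The 10 red genes inside the window lie on both sides of App, and Gm49708 lies at -5.67.

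31 lists of genes fixed beforehand were tested with camera, which compares a list with all other genes at a preset correlation of 0.01, and 9 passed an adjusted p of 0.05. In 29 of 100 splits of the 14 libraries, the real one included, as many lists passed. Immune lists rose. In the antigen presentation list, 16 of 17 measured members had positive log2 changes and 2 passed over all genes (4 adjusted over the list alone). B2m, the light chain of class I molecules, rose from 426 ± 79.7 to 728 ± 130 CPM (1.71-fold, edgeR adjusted p = 0.018). The immunoproteasome subunit Psmb10 rose from 45.2 ± 6.19 to 59.1 ± 5.73 CPM (edgeR adjusted p = 0.0495) and passed in 2 of the 14 fits without a library. The list's camera adjusted p was 1.19e-05 (adjusted p = 0.29 with an estimated correlation). Of the microglial activation and inflammatory genes 23 of 24 were positive, none passed over all genes and 7 did adjusted over the list alone, with the chemokine gene Ccl4 at 7.07 ± 3.20 and 12.7 ± 2.93 CPM and Nfkbia at 24.7 ± 4.43 and 33.2 ± 4.08 CPM (camera 0.00011, adjusted p = 0.29 with an estimated correlation). Of the 24 interferon response genes 22 were positive and 2 passed (7 adjusted over the list alone), the nucleic acid sensor Zbp1, 1.97-fold higher, and Xaf1, 1.61-fold higher (camera 0.00020, adjusted p = 0.65 with an estimated correlation). APPko library 3 stood apart in this list. Without it the list's median log2 change went from 0.54 to 0.26 (camera adjusted p = 0.015), and neither Zbp1 nor Xaf1 passed (both edgeR adjusted p = 0.060). Over the 14 fits without a library Zbp1 passed in 3 and Xaf1 in 2. Microglia markers passed as a list with 2 of 26 genes higher (6 adjusted over the list alone), namely Tyrobp from 54.7 ± 27.8 to 115 ± 19.7 CPM and C1qb from 123 ± 63.6 to 233 ± 45.0 CPM (camera 0.014, adjusted p = 0.65 with an estimated correlation). This call was lost in 4 of 22 other settings and without wildtype library 5 or 6 or APPko library 2 or 8 (camera adjusted p = 0.064, 0.056, 0.087 and 0.073). Tyrobp itself passed in 7 of the 14 fits without a library and C1qb in 3. With the header suffix as a covariate 6 lists passed.

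Reactive astrocyte genes and vascular markers also passed. The reactive astrocyte list shares H2-D1, H2-T23 and Psmb8 with the antigen presentation list, so these lists are not independent. Serping1, a complement inhibitor, was the only one of 28 reactive astrocyte genes to pass alone, from 18.7 ± 6.31 to 32.8 ± 5.84 CPM (4 adjusted over the list alone), and Psmb8 stood at 10.0 ± 2.15 and 13.9 ± 2.15 CPM (camera 0.00072, adjusted p = 0.51 with an estimated correlation). The reactive astrocyte call was lost in 4 of 22 other settings and without wildtype library 5 (camera adjusted p = 0.055). Of 22 vascular and fibroblast markers the basement membrane collagen gene Col4a2 passed (12.1 ± 3.32 to 19.2 ± 2.68 CPM, 2 adjusted over the list alone), and the pericyte marker Pdgfrb stood at 4.37 ± 1.77 and 7.23 ± 1.24 CPM (camera 0.038, adjusted p = 0.65 with an estimated correlation). The vascular list passed in 10 of 22 other settings, not without wildtype libraries 2 and 3 (camera adjusted p = 0.12) or with the GC trend removed (0.051). It also lost the threshold without wildtype library 3, 5 or 6 or APPko library 3 (camera adjusted p = 0.14, 0.055, 0.12 and 0.12). General astrocyte markers did not pass as a list (0.73). Atp1b2 (1.83-fold) and Ntsr2 (1.32-fold) rose (4 higher and 3 lower adjusted over the list alone). Atp1b2 passed in 8 of the 14 fits without a library and Ntsr2 in 2. The myelin list, led by Enpp2 and Myrf, and the oligodendrocyte precursor list, led by C1ql1 and Lhfpl3, did not pass (0.67 and 0.93) and held no gene past the threshold.

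Ribosomal protein genes formed the list with the smallest p. Of 83 measured genes 15 were higher and none lower (39 adjusted over the list alone), and 79 had positive log2 changes with a median of 0.30 (camera 2.9e-19, adjusted p = 0.42 with an estimated correlation). Rpl18 rose from 156 ± 27.9 to 239 ± 21.6 CPM, Rpl32 from 455 ± 99.5 to 750 ± 99.2 CPM, Rpl10 from 289 ± 44.0 to 423 ± 35.0 CPM and Rpl29 from 201 ± 18.1 to 286 ± 35.0 CPM. Their summed share of all counts was 2.57 ± 0.48% in wildtype and 3.39 ± 0.27% in APPko, and lay at 2.01% and 2.03% in wildtype libraries 2 and 3. These genes have many processed copies, and no source used here gives the treatment of multi-mapping reads. In a test added after the data were seen, each library was scored by the mean centred log2 CPM of a list, and 3 of the 31 lists had an adjusted p under 0.05. By exact permutation over all 3003 splits these were antigen presentation (score difference 0.40, p = 0.00067, adjusted 0.021), microglial activation (0.37, p = 0.0013, adjusted 0.021) and ribosomal protein genes (0.35, p = 0.0040, adjusted 0.041). Without wildtype libraries 2 and 3 no list passed this exact permutation test (differences of 0.41, 0.37 and 0.21, adjusted p = 0.10, 0.10 and 0.19). With the GC trend removed microglial activation passed (0.33, exact permutation adjusted p = 0.041), and antigen presentation and ribosomal protein genes did not (0.25 and 0.29, exact permutation adjusted p = 0.10 and 0.062).

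**Figure D3:**
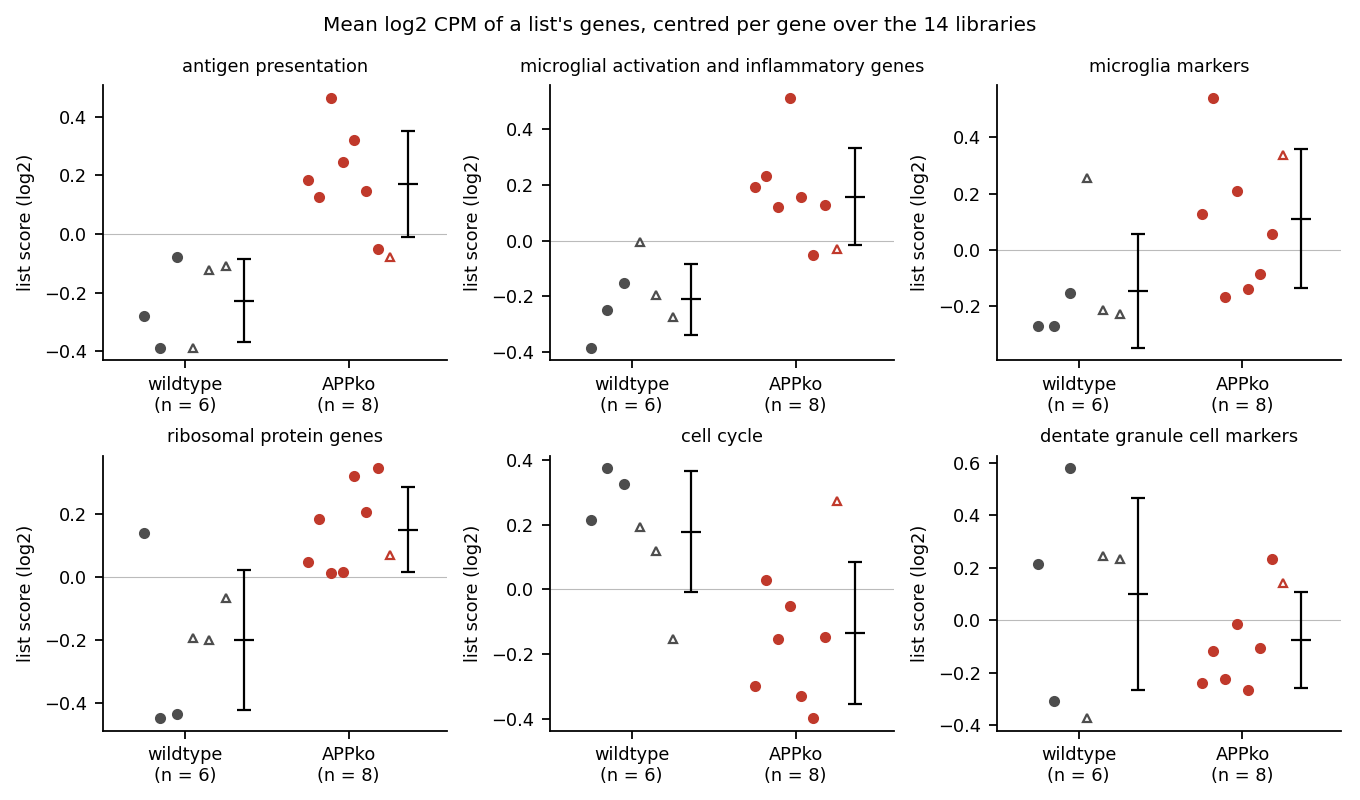
List score of each library (y axis, mean log2 CPM of a list's genes after centring each gene over the 14 libraries) for 6 gene lists in wildtype (grey, n = 6) and APPko (red, n = 8), with the mean ± SD beside the points, circles for header suffix f and triangles for m. Antigen presentation scores average -0.23 ± 0.14 in wildtype and 0.17 ± 0.18 in APPko, while granule cell scores overlap widely.

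2 lists fell. Of 24 cell cycle genes 21 had negative log2 changes and 2 passed (3 adjusted over the list alone): Top2a, the topoisomerase of dividing cells, 1.71-fold lower at 9.36 ± 2.49 CPM, and the proliferation marker Mki67 from 13.5 ± 2.73 to 8.84 ± 1.72 CPM (camera 7.1e-05, adjusted p = 0.51 with an estimated correlation). Top2a and Mki67 each passed in 4 of the 14 fits without a library. Their log2 changes were -1.15 and -0.84 in f libraries and 0.13 and 0.030 in m libraries. The list passed camera in all 22 other settings. Its score did not pass (exact permutation adjusted p = 0.12, and 0.38 without wildtype libraries 2 and 3). Scores were highest in wildtype libraries 2 and 3 (0.37 and 0.33). The only APPko m library scored 0.27, against -0.15 to 0.19 in m wildtype libraries. Of 22 dentate granule cell markers 4 fell and none rose (7 lower and 1 higher adjusted over the list alone). They were the transcription factor gene Rfx3 (180 ± 29.8 to 126 ± 16.3 CPM), the neuropeptide Y receptor gene Npy1r (72.3 ± 12.1 to 43.3 ± 11.8 CPM), C1ql3 (30.7 ± 9.71 to 17.9 ± 4.84 CPM) and Ntng1 (1.46-fold lower from 29.1 ± 5.01 CPM), with camera 0.025 (adjusted p = 0.65 with an estimated correlation). Rfx3 and Npy1r each passed in 6 of the 14 fits without a library, C1ql3 and Ntng1 each in 2. The granule cell list passed in 15 of 22 other settings, not without wildtype libraries 2 and 3 (camera adjusted p = 0.063), and lost the threshold without wildtype library 3, 5 or 6 (0.19, 0.055 and 0.056). The markers of mossy cells and CA fields, led by Bok and Calcrl, and of immature neurons, led by Igfbpl1 and Ncam1, did not pass (0.53 and 0.85) and held no called gene.

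Receptor and channel lists did not pass camera. Of 20 GABA-A receptor and inhibitory synapse genes, Gabra2 rose from 227 ± 73.5 to 388 ± 85.8 CPM and the scaffold gene Iqsec3 from 32.2 ± 8.69 to 52.6 ± 6.62 CPM (camera 0.051, 2 higher and 4 lower adjusted over the list alone). Gabra2 passed in 3 of the 14 fits without a library and Iqsec3 in 8, and each passed in 17 of 23 other settings. Of 49 sodium, potassium and HCN channel genes 6 were lower and 2 higher (16 and 5 adjusted over the list alone), among them Kcnj3, a G protein-gated potassium channel, from 200 ± 34.6 to 125 ± 16.3 CPM, Scn3a and Kcna4, 1.44- and 1.55-fold lower, and Hcn2, 2.52-fold higher at 1.94 ± 0.37 CPM (camera 0.051). Grm5, the metabotropic glutamate receptor 5, fell from 442 ± 107 to 273 ± 37.9 CPM and Kctd8, a GABA-B receptor subunit, from 5.68 ± 1.06 to 3.38 ± 0.42 CPM, in a list of 12 (4 lower adjusted over the list alone). This list did not pass camera (0.24, adjusted p = 0.51 with an estimated correlation) and did pass fry, a directional test within the list (limma adjusted p = 0.019). Its score did not pass (exact permutation adjusted p = 0.18). Of 38 AMPA, NMDA and kainate receptor genes only Gria4 passed, 1.48-fold lower (also 1 adjusted over the list alone), and Gria2 stood at 1528 ± 244 and 1181 ± 111 CPM (adjusted p = 0.076, camera 0.93). Of 48 postsynaptic and adhesion genes Ptprs and Ppp1r9b rose 1.41- and 1.82-fold and 4 fell, Lrrtm3 and Slitrk2 among them by 1.68- and 1.53-fold (camera 0.46, 2 higher and 8 lower adjusted over the list alone). Of 52 presynaptic genes Slc17a6, the vesicular glutamate transporter VGLUT2, fell 1.80-fold, and Syn1 stood at 84.3 ± 12.9 and 115 ± 20.1 CPM (adjusted p = 0.065, camera 0.42, 4 higher and 2 lower adjusted over the list alone). The calcium channel list held Cacnb4, 1.43-fold lower, and Cacnb1, 1.85-fold higher (camera 0.95, 2 each way adjusted over the list alone). The interneuron list, led by Pvalb and Adarb2, held no called gene (camera 0.059).

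The genes tied to App processing moved little as a group. Of 24 members Adam10, which encodes the main alpha-secretase, fell 1.40-fold from 153 ± 36.6 to 110 ± 7.72 CPM (adjusted p = 0.044), and Bace2 stood at 5.95 ± 0.94 and 8.15 ± 1.92 CPM (adjusted p = 0.13, camera 0.80, 1 adjusted over the list alone). Adam10 passed in 3 of 14 fits without a library and in 11 of 23 other settings. It was highest in wildtype libraries 2 and 3 (216 and 172 CPM). Wildtype library 4, at 111 CPM, lay within the APPko range of 98.1 to 118 CPM. Of 10 measured genes proposed as targets of the App intracellular domain, Slc17a6 alone passed, and Gsk3b stood at 383 ± 117 and 263 ± 33.7 CPM (adjusted p = 0.071, camera 0.42, 2 adjusted over the list alone).

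The called genes differed in base composition. The median transcript GC content was 54.1% for genes higher in APPko, 43.2% for genes lower and 48.0% for genes that did not pass. Wildtype libraries 2 and 3 had the strongest trend with GC: from the lowest to the highest sixth of genes by GC content their median expression relative to all libraries changed by -0.91 and -0.58 (log2), against values from -0.18 to 0.34 in the other libraries. With a GC trend removed from each library, a setting chosen after the data were seen, 85 genes were higher and 109 lower, and 163 of the 521 were among them.

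**Figure D4:**
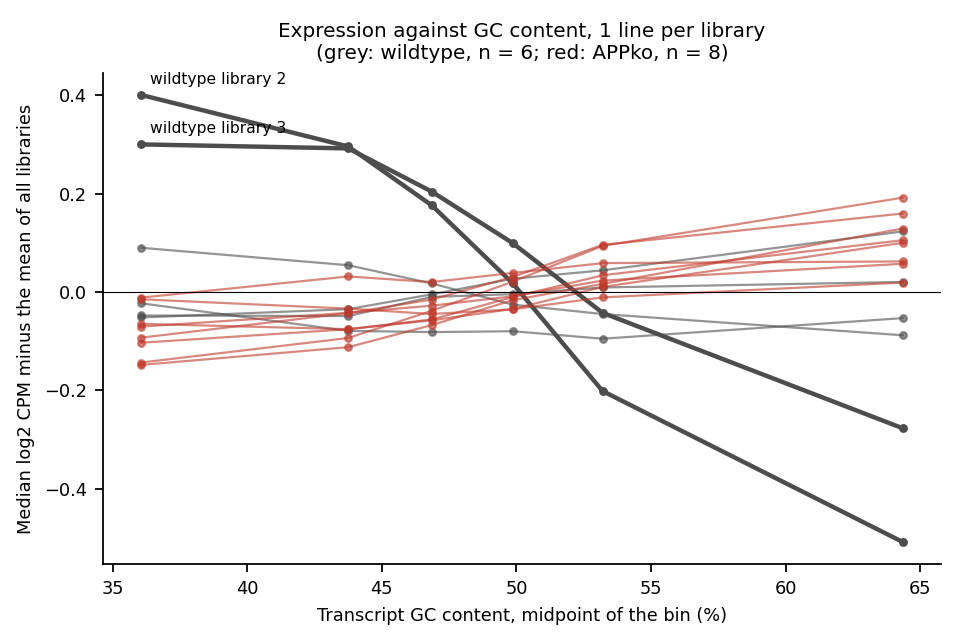
Median log2 CPM relative to the mean of all libraries (y axis) in 6 bins of transcript GC content (x axis, bin midpoint in %), with 1 line per wildtype (grey, n = 6) or APPko (red, n = 8) library and 1732 to 1735 genes per bin. The thick lines of wildtype libraries 2 and 3 start at 0.40 and 0.30 and end at -0.51 and -0.28.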

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

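The tests of trends over GC content and gene length, of the sex mix, of a regulatory element and of the microglia and GC explanations for antigen presentation were chosen after the results were seen, as was the header suffix interaction. Each genotype's highest or lowest library was checked for a gap to its neighbour that is large against the group's range. 19 of 292 groups exceeded the 95% bound (16 of 218 for named genes, 0 of 12 for library measures, 3 of 62 for list scores), where chance gives about 5%.

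APPko library 8, the only APPko library with suffix m, stood apart in 6 genes. Ddx3y, Eif2s3y and Kdm5d were at 127, 165 and 42.3 CPM there and at most 1.63, 2.39 and 0.65 CPM in the other APPko libraries (gaps of 0.993, 0.988 and 0.985 of the range), and Xist was at 2.22 CPM against at least 138.5 CPM (0.663). Wdfy1 was at 49.5 CPM in this library and at least 73.9 CPM in the others (0.658), and Rpl29 was highest there at 358 CPM (0.5262). Among the other APPko libraries, Ccl4 was highest in library 3 (19.2 CPM, 0.599), Ifitm3 and Hspb1 in library 5 (339 and 45.1 CPM, 0.606 and 0.528) and mt-Nd4l in library 7 (8.31 CPM, 0.581). In wildtype, library 1 had the highest Hspb1 (34.2 CPM, 0.718) and the lowest Npy1r (48.8 CPM, 0.735), and Calcrl was highest in library 2 (58.8 CPM, 0.643), Scn3a in library 3 (154 CPM, 0.664), Gpx3 in library 4 (97.9 CPM, 0.791) and Zbp1 in library 5 (4.40 CPM, 0.655). Among list scores, the App processing list was highest in APPko library 2 (0.588), interferon response in APPko library 3 (1.22 against 0.30 for the next, 0.556) and microglia markers in wildtype library 4 (0.25 against -0.15, 0.779).

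The log2 change of Gpc1 was 2.75 in f libraries and 0.69 in m libraries, an interaction of -2.06 (edgeR adjusted p = 0.043). Only 1 APPko library carries m, and the test assumes that it varies like the other libraries, so this value does not show that the effect depends on the suffix. Over all genes 411 had an adjusted interaction p under 0.05, and wildtype libraries 2 and 3, which both carry f, enter the same contrast.

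The differing GC content of higher and lower genes was weighed as a pattern. Removing the length trend left 62.4% of the 521 calls. Higher and lower calls in that setting still had a median GC content of 54.1% and 43.7%. This argues against the length trend as the source of the differing GC content. It does not show how many calls rest on gene length, since the GC trend stayed in place. Called genes also differed in exon length (median 2137 bp for higher, 5820.5 bp for lower and 3486 bp for genes that did not pass). The suffix covariate left 95.4%, and f libraries alone, where the suffix does not vary, kept 464 of the 521. This argues against the sex mix as the source of most calls. With only 1 APPko library in m, both settings rest mostly on the f libraries. Wildtype libraries 2 and 3 are among the 3 wildtype f libraries, so these settings do not tell genotype from their deviation. Removing the GC trend left 31.3%, while the median absolute log2 change of the 521 genes went from 0.67 to 0.59 with a median SE of 0.15 before and after. The median p of these genes went from 0.00043 to 0.0011 (edgeR), and why each call ended was not tested, since the adjusted threshold also tightens as fewer genes pass. All 521 kept their direction. A technical GC trend per library may have carried many genes across the threshold. Most of their fold remained without it, but the 521 genes were picked by their p in the same libraries. Kept folds and directions are therefore little support. Without wildtype libraries 2 and 3 their median absolute log2 change was 0.49. With the GC trend also removed it was 0.43, and 18 of the 521 calls remained. Wildtype libraries 2 and 3 are not the whole source of the GC trend. Without them the higher and lower calls still had a median GC content of 52.7% and 41.9%. The log2 change also still correlated with GC content (Spearman 0.29, against 0.53 with all libraries). A genotype effect that itself follows GC content would be removed by the same step and stays open. Chance is an unlikely source of the count as a whole: 1 of 100 drawn splits of the 14 libraries, the real one, gave 521 genes, and the highest other gave 5. These were 100 of 3003 possible splits. They treat the cultures as interchangeable, though which of them shared an animal is not known.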

How the results depend on the processing

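App stayed lower in all 23 settings and all 14 fits without a library (log2 change -2.003 to -1.77 over settings). The settings named here with GC content, the header suffix or wildtype libraries 2 and 3 were chosen after the data were seen. The counts of genes depended strongly on the setting, and the cause was not tested except where stated. Higher and lower genes numbered 749 and 1052 with DESeq2, 793 and 820 with Y-linked expression as a covariate, 718 and 728 with the header suffix, 1674 and 1998 in f libraries alone, 139 and 207 without the length trend, 85 and 109 without the GC trend, and 19 and 16 without wildtype libraries 2 and 3 (11 and 9 with the GC trend also removed). A test against a fold of 1.2 gave 7 and 7, which asks for more by construction. Higher and lower genes numbered 448 and 465 with 1 surrogate variable, 182 and 170 with voom, 304 and 170 without a filter and 195 and 190 without the neighbourhood of App, against 209 and 312 in the report. Between 22 and 735 genes were higher and between 16 and 701 lower when single libraries were left out. The totals were 967, 87, 66, 1436, 615 and 451 without wildtype libraries 1 to 6 and 83, 77, 410, 125, 38, 146, 56 and 312 without APPko libraries 1 to 8. 38 of the 521 genes passed in each of these 14 fits. All 521 kept their direction with DESeq2, with voom, with the GC trend removed and in each fit without a library. They were picked in the same libraries, so this is little support for them. The smaller groups of single fits cost power, but the larger counts without wildtype libraries 1 and 4 show that sample number alone does not set them.

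The odds ratio near App was 1.00 with DESeq2, 1.51 with Y-linked expression, 1.41 with the suffix, 1.96 with the suffix and no GC trend, 1.11 in f libraries alone and 3.47 in a 2 Mb window, none past the threshold (Fisher's exact p from 0.10 to 1.00). In the 2 Mb window 1 of 13 genes was called, Gm49228 inside App. Without single libraries it ran from 1.73 (without wildtype library 4, Fisher's exact p = 0.064) to 36.4. Camera put 0 lists past the threshold with an estimated correlation (3 at an unadjusted p under 0.05) and fry put 4, against 9 with the preset correlation. Without single libraries 5 (without wildtype library 5) to 12 lists passed. Among named genes outside the fits without a library, 1808 values kept their direction and side of the threshold, 546 lost the threshold and 69 gained it.

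7 named genes and 14 lists changed direction in some setting, by the sign of the log2 change for genes and by camera's direction for lists, whose median log2 change is printed. Of the lists, oxidative phosphorylation in f libraries alone passed the threshold (-0.16, camera adjusted p = 0.029). Aplp2 was at 0.019 with upper-quartile scaling, 0.037 without a filter, 0.0088 with the stricter filter, 0.014 in protein-coding genes, 0.0079 without mitochondrial genes, 0.012 without the neighbourhood of App, 0.015 with a surrogate variable, 0.033 with Y-linked expression, 0.0051 in thinned libraries, 0.018 without the GC trend, 0.042 with the suffix, 0.073 with the suffix and no GC trend, 0.079 in f libraries, 0.010 without wildtype libraries 2 and 3 and 0.0029 with the GC trend also removed. Aplp1 was at -0.011 without the GC trend. With the suffix, Ddx3y, Eif2s3y and Kdm5d were at 0.26, 0.37 and 0.43, with the GC trend also removed at 0.40, 0.50 and 0.47, and with Y-linked expression Eif2s3y and Kdm5d were at 0.020 and 0.29, while in f libraries Ddx3y and Eif2s3y were at 0.70 and 0.77. Calcrl and Myrf were at 0.064 and -0.0029 without wildtype libraries 2 and 3 and the GC trend.

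The voom fit put the myelin list at -0.064. Without a filter the ionotropic glutamate receptor and calcium channel lists were at 0.078 and 0.029, with the stricter filter the calcium channel list at -0.0017, and without the neighbourhood of App the ionotropic list at 0.056. Without the length trend the ionotropic, postsynaptic, calcium channel, oligodendrocyte precursor, oxidative phosphorylation and mitochondrial lists were at 0.0058, -0.0061, -0.040, -0.068, -0.055 and -0.015. A surrogate variable put the calcium channel list at -0.037. With Y-linked expression the ionotropic, calcium channel, precursor, matrix and oxidative phosphorylation lists were at 0.080, -0.065, 0.0047, -0.0052 and -0.045. With the suffix the ionotropic, precursor, matrix and oxidative phosphorylation lists were at 0.075, 0.013, -0.014 and -0.072. With the suffix and no GC trend the activity-regulated, astrocyte, matrix and oxidative phosphorylation lists were at -0.0031, -0.0099, -0.076 and -0.11. Without the GC trend the App processing, activity-regulated and matrix lists were at -0.019, -0.045 and -0.062. In f libraries the calcium channel, astrocyte and matrix lists were at 0.036, -0.024 and 0.070. Without wildtype libraries 2 and 3 the activity-regulated, mossy cell and myelin lists were at -0.073, 0.026 and -0.076. With the GC trend also removed the App processing, presynaptic, activity-regulated, myelin and matrix lists were at 0.023, -0.0098, -0.090, -0.10 and 0.011.

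Without single libraries Aplp2 ran from -0.049 to 0.070, and the lists ran from -0.066 to 0.12 (ionotropic), -0.13 to 0.019 (postsynaptic), -0.10 to 0.13 (calcium channel), -0.074 to 0.070 (immature neuron), 0.026 to 0.14 (astrocyte), -0.028 to 0.15 (myelin), -0.12 to 0.12 (precursor), 0.0047 to 0.12 (matrix) and -0.048 to 0.046 (oxidative phosphorylation).

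The labels do not say what the shared replicate numbers mean, and not every pair of same-numbered libraries deviated together. Their deviations correlated at 0.18, 0.045, -0.34, 0.19, 0.16 and 0.0089, 3 of 6 over 0.1, and 1 of 6 wildtype libraries correlated best with its own number. With the replicate block, 10 genes were higher and 11 lower, with the length trend also removed 5 and 8, and with the GC trend also removed 9 and 8. With the block Aplp2 was at 0.014 and the mitochondrial list at 0.045. With block and no length trend Aplp2 was at 0.0070 and the calcium channel, oxidative phosphorylation and mitochondrial lists at -0.0031, -0.049 and -0.023. With block and no GC trend Aplp1 and Aplp2 were at -0.049 and 0.033, and the App processing, activity-regulated, astrocyte, myelin, matrix and oxidative phosphorylation lists at 0.0025, 0.00061, -0.0049, 0.032, 0.024 and -0.061.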

Other observations

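Several gene groups outside the main text held single genes that moved. Mt1, a metal-binding stress protein, rose 1.97-fold from 1516 ± 492 to 2984 ± 693 CPM, in a heat shock and dissociation stress list of 13 with no other called gene (camera adjusted p = 0.31, 2 adjusted over the list alone), where Hspb1 stood at 15.6 ± 9.50 and 28.0 ± 7.80 CPM. Ddit3, the stress-induced factor CHOP, rose 1.33-fold from 47.1 ± 5.39 to 62.5 ± 7.99 CPM as the only called gene of 24 in the unfolded protein list, which also held Shmt2 at 17.0 ± 4.23 and 24.3 ± 3.499 CPM (camera 0.080, 4 higher and 1 lower adjusted over the list alone). In the oxidative phosphorylation list 3 of 70 genes rose, Atp5g2, Cox8a and Cox6a1 by 1.56-, 1.56- and 1.63-fold, while the list did not pass (camera 0.43, 5 higher adjusted over the list alone) and Sdhc stood at 92.3 ± 25.7 and 132 ± 14.6 CPM. Its median log2 change was -0.0070 and its mean 0.0084. Of 13 mitochondrially encoded genes mt-Co3 fell from 113 ± 31.0 to 72.3 ± 5.09 CPM and mt-Nd4l stood at 3.51 ± 1.24 and 5.12 ± 1.48 CPM (camera 0.73, 1 lower adjusted over the list alone).

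In cholesterol synthesis and uptake, Insig1, a sensor of sterol levels, fell 1.70-fold from 75.4 ± 25.5 to 44.3 ± 9.99 CPM, and the list of 25 did not pass (camera 0.42, 1 higher and 2 lower adjusted over the list alone). Among 38 activity-regulated genes Nr4a2 fell 2.02-fold and the phosphatase gene Dusp5 rose 1.99-fold (camera 0.42, 1 each way adjusted over the list alone). In the brain extracellular matrix list of 25, Hapln4 of perineuronal nets rose 1.68-fold and Ptprz1 stood at 506 ± 84.9 and 378 ± 45.0 CPM (camera 0.95, 1 higher and 2 lower adjusted over the list alone).

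The neighbourhood of App was weighed as a pattern, with the strain and splits tests chosen before their results were seen and the regulatory test after. 1 of 100 splits, the real one, called 10 genes within 10 Mb, and the highest other called 0. The other splits called at most 5 genes in all, so this count says nothing about clustering near App. A segment of another strain's chromosome 16 carried along with the targeted allele is a candidate explanation, with an odds ratio of 3.73 in the direction it predicts, though the odds ratio was 1.00 with DESeq2. Loss of a regulatory element inside App cannot be told apart from it: 0 of 11 genes within 2 Mb outside App were called against 9 of 110 at 2 to 10 Mb (Fisher's exact p = 1.00), too few genes to decide. Wdfy1 and Gabra2, which rose on chromosomes 1 and 5, were tested for a line-wide difference in strain through Nnt, which carries a deletion in C57BL/6J. Nnt was at 24.3 ± 5.31 CPM in wildtype and 19.6 ± 2.35 CPM in APPko (log2 change -0.31, 95% interval -0.58 to -0.041). The rise predicted for other alleles across the whole line was thus not seen at this locus. Counts summed over the gene do not show which genotype carries the deletion, so a single locus does not decide for the line. Strain segments at other loci stay open.

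The rise of antigen presentation genes was weighed as a pattern, with both tests chosen after the result was seen. More microglia in APPko cultures may raise the list, yet the microglia score was 0.26 higher (exact permutation p = 0.060) and the antigen presentation score 0.40 higher, and the difference between the 2 scores did not pass (exact permutation p = 0.45), so the 2 cannot be told apart. The lists share 0 members. With the GC trend removed the list still passed camera (adjusted p = 0.0037), which argues against the trend as the whole source by the criterion set for this test. A second measure, the score, did not pass: its difference went from 0.40 to 0.25 (exact permutation p = 0.019, adjusted p = 0.10 over the 31 lists), so a part through GC content stays open. With the header suffix also as a covariate the list did not pass camera (adjusted p = 0.12). A genotype effect on immune genes and a linked strain difference were not tested apart. The count of lists cannot be set against chance in favour of the genotype: 29 of 100 splits put 9 or more lists past camera's preset threshold, and the highest other split put 16.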
